A study of Homo sapiens with 6 samples.

How the data were processed

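Single nuclei of frozen human left ventricle were measured in 3 donor samples and 3 NICM samples. The authors isolated nuclei with a column kit, sorted them on a DNA dye, dispensed them with the ICELL8 cx system and made SMART-Seq Pro libraries. The authors counted reads on the GRCh38 build, per the submitters' processing notes. The deposited count tables hold whole reads per gene and nucleus barcode, introns included, with no scaling applied by the authors. The chemistry has no molecular identifiers, so copies of a fragment made by amplification are counted as reads. A further deposited table gives gene length in bases, with identifiers, symbols and biotypes, per the file headers. The aligner, the counting tool, the strand setting and any prior filter on barcodes are not given in the sources. How reads of overlapping genes were counted is therefore not known: 51 of the 77 genes named by the rule below overlap another gene. Olfactory receptor genes over 3 kb held fewer reads per kb where fully under other genes, so counts of overlapping genes may be low. Coordinates are those of the reference annotation, counted from 1 on GRCh38.

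Nuclei were kept with at least 500 genes detected, at least 5000 reads counted to genes and at most 10% mitochondrial reads. This kept 2071, 1590 and 1762 of 2147, 2035 and 2130 barcodes in donor replicates 1 to 3, and 1230, 2182 and 2005 of 1957, 2270 and 2093 in NICM replicates 1 to 3. The mitochondrial limit left out 0, 371 and 320 barcodes of the donors and 677, 17 and 0 of the NICM samples. Median reads per kept nucleus were 244801, 300074 and 315890 in donors and 367450, 232446 and 259660 in NICM. Median genes were 15339, 12603.5 and 11234.5 in donors and 12219, 12639 and 14925 in NICM. The biological coefficient of variation fitted by edgeR to the sums was 0.528 to 0.694, so the spread between samples limits the precision of each comparison.

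For clustering, counts of protein-coding, lincRNA and antisense genes outside the mitochondrial genome were scaled to 10000 per nucleus and log-transformed in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19). The 2000 most variable genes, chosen within samples, gave 30 principal components and 15 neighbours, and Leiden clustering ran at a resolution of 2 (leidenalg 0.10.2, igraph 0.11.9), with no integration across samples. A cluster took the class whose markers had the highest mean log2 fold of mean CPM + 20 against the median cluster. It needed 3 markers at a log2 fold of 1 or more, a mean of at least 1.2, and 2 of its own markers among its top 10 genes. No other class could have more of its markers there. These thresholds were set after the clusters were seen. Markers of erythroid, B and plasma, mesothelial and smooth muscle cells were also searched, and no cluster took those names.

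Reads were summed per sample and class where at least 20 nuclei were present, which held for all samples in each of the 6 comparisons. Sums were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr on the group, TMM factors, glmQLFit and glmQLFTest, NICM against donor, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference in effect between cardiomyocyte-like and fibroblast-like nuclei was the interaction of class and group, with the sample as a block. Shares and quality measures were compared by exact two-sided permutation over the 20 assignments of 3 samples against 3. CPM values in the comparisons are per 1000000 reads of TMM-scaled library size. Levels of NPPA and other cardiomyocyte transcripts set against cardiomyocyte-like nuclei of the same sample are per 1000000 reads without TMM factors. With library size alone, the median log2 fold of all genes lay at 0.18 to 0.32 over the 6 comparisons. With TMM factors but without donor replicate 1 it lay at 0.11 to 0.22. The edgeR fit was tested on simulated data, counts drawn at the spread of these samples with 200 genes changed by a fold of 2 or 4, and its recovery is given with the results.

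Lists of genes for 23 processes and cell types, the genes to be named and the comparisons were fixed before the data were examined. Each list was tested by camera (limma 3.58.1) with a preset correlation of 0.01 on edgeR's fit, adjusted over 138 tests. Camera with an estimated correlation and fry were run beside it, and a list needed 5 tested members. The rule named, in each comparison, the 10 genes higher and 10 lower with the largest folds among those that passed, and up to 4 passing members of each list. It also named genes fixed by name, and where under 3 genes passed, the 5 of smallest p. Genes named by fold, and the 5 of smallest p, needed a mean of 16 CPM or more and separated groups. List members needed only to pass, and genes fixed by name had no condition. No gene passed in the main edgeR fits, so the 5 of smallest p are given. Members given as examples of a list (HSPA1A, BAG3, FGF7, CD248, ICAM1, TNC, VCAN, LYZ and HIF1A) were chosen after their values were seen. Genes that can mark a person were left out of all names.

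Alternatives fixed in advance were DESeq2 1.42.0, library size alone, no filter on low counts, nuclei thinned to 5000 reads, and limma on mean log values per nucleus. Others were 1000 genes per nucleus, a mitochondrial limit of 5% or none, Scrublet doublets left out, clusters made per sample, shares among named nuclei alone, and each sample left out in turn. Chosen after seeing the data were genes at 16 CPM or more only, the background density as a covariate, the background subtracted, and donor replicates 2 and 3 against NICM replicates 1 and 2. The sums over all nuclei without the clusters led by PRAME were also chosen after seeing the data. The background of a sum was the pooled reads per base of 384 olfactory receptor genes, those named OR51E left out, times the length of each gene. Summed counts of each pair of samples differed with a chi-square of 647 to 4584 per degree of freedom. This sets separate samples against counting error alone, in reads that include amplified copies, so a value far above 1 was expected and shows only that no 2 samples hold the same counts. Samples of a group shared 813 to 954 barcodes and samples of different groups 0. The labels give each sample a distinct library and do not pair donors with NICM samples. They do not say whether each library comes from a different person. Figures were drawn with matplotlib 3.10.9.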

Results

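The series measured gene expression in single nuclei from frozen human left ventricle, in 3 donor samples and 3 samples with non-ischemic cardiomyopathy (NICM), heart failure without a coronary cause. Nuclei carrying a DNA dye were sorted and dispensed into nanowells of the ICELL8 cx system, where full-length SMART-Seq Pro libraries were made from each. The labels state that NICM tissue came from cores removed for a ventricular assist device and donor tissue from the matching region of the apex, so the way the tissue was obtained differed with the group. The tables held between 1957 and 2270 barcodes per sample. Reads counted to genes, introns included, came to 673088847, 669050710 and 766018385 in donor replicates 1 to 3 and 762606802, 754775754 and 639907769 in NICM replicates 1 to 3. The question addressed is how gene expression and the makeup of nuclei differ between NICM and donor ventricle. The labels do not say whether each sample came from a different person, and the 6 samples were treated as 6 independent ones. P-values of genes, shares and quality measures below therefore measure only the spread between these samples, which may be technical in part. Those of camera set the members of a list against the other genes. With the preset correlation they rest on an assumed correlation between genes and do not measure that spread. The errors beside means are SDs over 3 samples and those beside log2 folds are standard errors.

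Reads and genes per nucleus overlapped between the groups. The median reads per kept nucleus averaged 286922 ± 37325 in donors and 286519 ± 71398 in NICM (SD, n = 3 each, exact two-sided permutation p = 1). Median genes detected averaged 13059 ± 2089.8 in donors and 13261 ± 1456 in NICM (exact permutation p = 0.9), and mitochondrial reads 3.6% ± 2.67 and 2.84% ± 2.34 (p = 0.9, exact permutation test). Nuclei kept per sample averaged 1808 ± 244 and 1806 ± 506 (exact permutation p = 1). Each of these 4 adjusted p-values was 1, and 3 samples against 3 cannot give an exact p below 0.1. Samples of the same group stood apart in another respect. Olfactory receptor genes, a family expressed mainly in olfactory tissue, carried reads in every sample. The 384 genes used leave out those named OR51E, and their pooled read density was below their median density in each sample. At that pooled density per base, all genes together would hold 61.9%, 26.1% and 15.2% of the reads of donor replicates 1 to 3 and 21.7%, 43.3% and 80.3% of those of NICM replicates 1 to 3. That percent depends on the family: in NICM replicate 3 it was 52.5 by keratin-associated protein, 70.6 by beta-defensin and 11.2 by taste receptor genes, which put all 6 samples at 8.6 to 11.2. Genes that overlap no other gave 97.7 by olfactory receptor and 107.5 by keratin-associated protein genes there, so it is an index and not a measured share of reads. Donor replicate 1, NICM replicate 2 and NICM replicate 3, with the highest such percents, also had the most genes per nucleus (15339, 12639 and 14925 against 11234.5 to 12603.5 in the other 3).

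**Figure D1:**
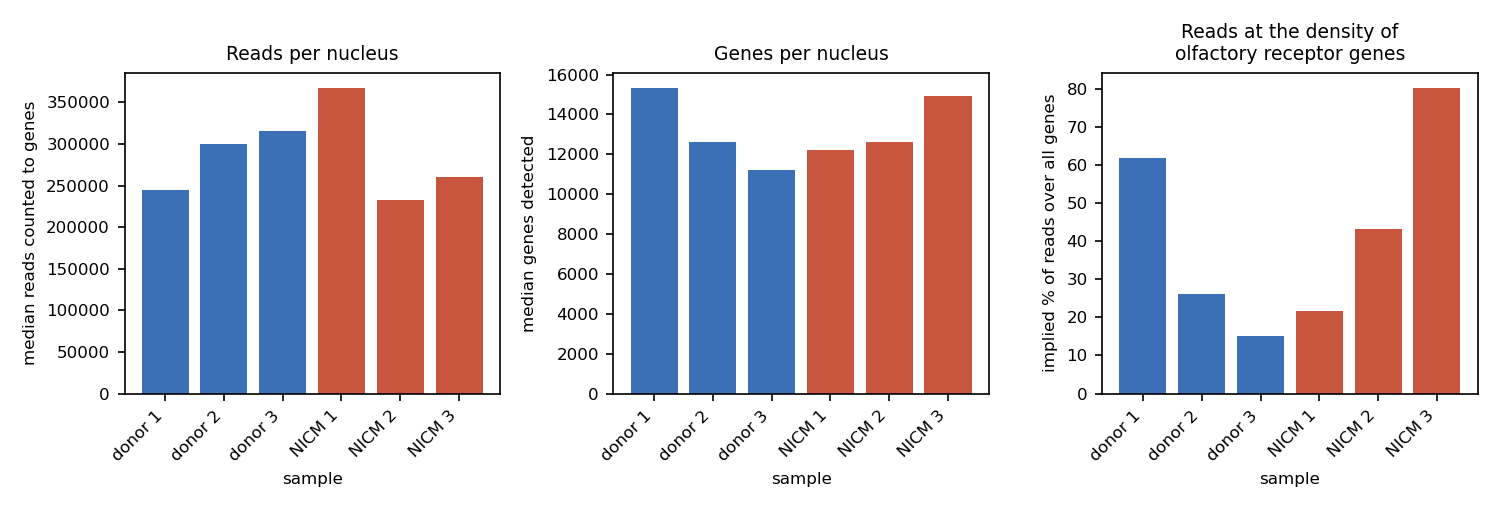
Bars give, for each sample, the median reads per kept nucleus, the median genes detected per kept nucleus, and the percent of reads that all genes would hold at the pooled read density of olfactory receptor genes, an index that depends on the family used. That percent runs from 15.2 in donor replicate 3 to 80.3 in NICM replicate 3, and both groups hold samples with low and high values.

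Marker genes placed 9156 of 10840 kept nuclei in 11 named classes, each called by the class whose markers it carried. Fibroblast-like nuclei (2160) and endothelial-like nuclei (2103) were the most numerous, followed by cardiomyocyte-like (86 to 360 in each sample), pericyte-like (1255) and myeloid-like nuclei (1147). Pericyte-like nuclei made up 15.4% ± 7.69 of donor and 7.88% ± 3.06 of NICM nuclei, and cardiomyocyte-like nuclei 15.2% ± 5.67 of donor and 10.5% ± 7.50 of NICM nuclei (SD, n = 3 each). Fibroblast-like nuclei made up 17.9% ± 4.32 of donor and 22.6% ± 8.00 of NICM nuclei, myeloid-like nuclei 8.72% ± 1.53 of donor and 11.7% ± 3.83 of NICM nuclei, and endothelial-like nuclei 20.4% ± 5.51 of donor and 20.4% ± 7.91 of NICM nuclei. Endocardial-like nuclei made up 6.06% ± 1.78 of donor and 3.13% ± 3.33 of NICM nuclei, and lymphoid-like nuclei 1.96% ± 1.00 of donor and 3.42% ± 1.67 of NICM nuclei. Lymphatic-like nuclei made up 0.527% ± 0.171 of donor and 1.57% ± 1.01 of NICM nuclei, adipocyte-like nuclei 0.271% ± 0.273 of donor and 1.28% ± 0.893 of NICM nuclei, neuronal-like nuclei 0.803% ± 0.732 of donor and 0.581% ± 0.452 of NICM nuclei, and mast-like nuclei 0.637% ± 0.798 of donor and 0.199% ± 0.344 of NICM nuclei. Nuclei without a name made up 12.2% ± 14.4 of donor and 16.8% ± 13.6 of NICM nuclei, and most of them came from donor replicate 1 and NICM replicate 3 (28.8% and 32.5% of their nuclei). Single samples moved the NICM minus donor difference from -7.48 percentage points to -3.40 without donor replicate 2 and -11.0 without donor replicate 1 for pericyte-like nuclei, from -4.66 to -1.53 without NICM replicate 3 and -8.81 without NICM replicate 1 for cardiomyocyte-like nuclei, and from 4.61 to -3.27 without NICM replicate 3 and 12.9 without donor replicate 1 for unnamed nuclei. In the exact two-sided permutation test no share passed, with p from 0.2 to 1 and adjusted p of 0.6 or more over 12 classes. The unnamed nuclei include 136 and 105 in a pair of clusters led by PRAME, and the sources do not say whether control cells were dispensed with the tissue nuclei. Shares describe captured nuclei, since the nuclei were sorted and dispensed, and the thresholds for naming a cluster were set after the clusters were seen. A cluster of 218 nuclei close to the endothelial threshold stayed unnamed. It held 105, 6 and 1 nuclei of donor replicates 1 to 3 and 4, 31 and 71 of NICM replicates 1 to 3. Its leading genes were ITGB2, AREG, NAMPT, PTPRB, SLC11A1, VWF, SRGN, TLR2 and FCN1. Of these PTPRB and VWF are endothelial markers, and AREG and FCN1 belong to the list of monocyte-derived cell genes, so it is not read as endothelial.

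**Figure D2:**
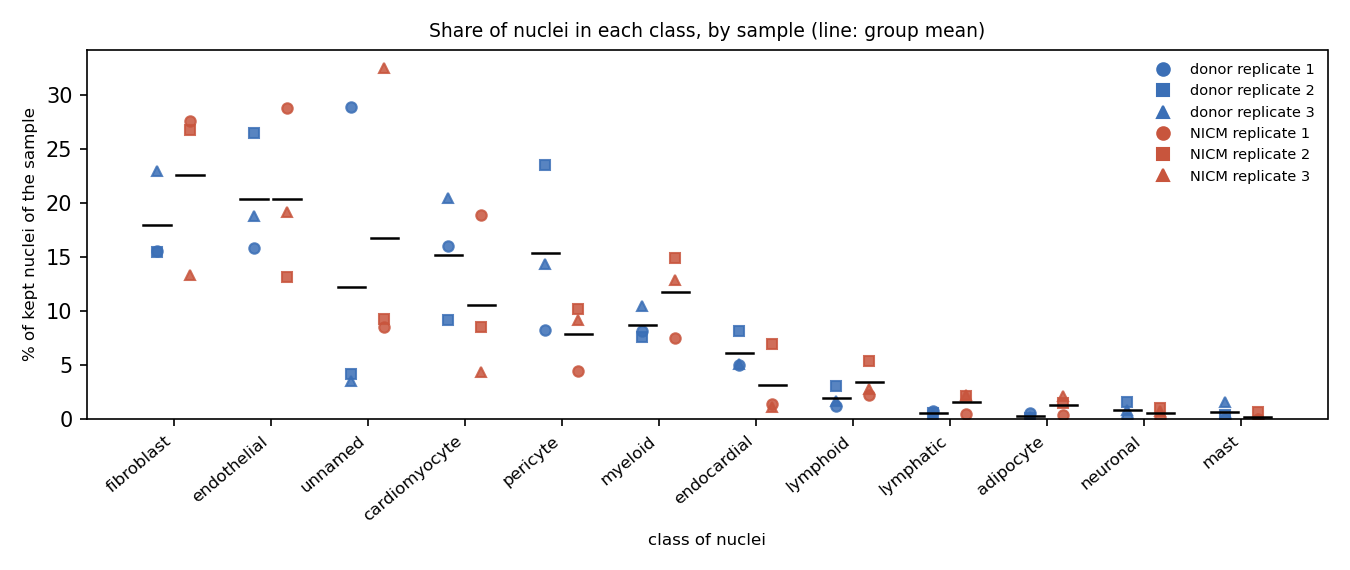
Each point is the percent of a sample's kept nuclei that fall in a class, with donor samples in blue and NICM samples in red, and each line is the mean of 3 samples. The groups overlap in each class, and unnamed nuclei are most frequent in donor replicate 1 and NICM replicate 3.

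In cardiomyocyte-like nuclei, immediate early and heat shock genes stood lower in NICM than in donors, with medians of -2.90 and -2.55 on the log2 scale. Camera called both lists with a preset correlation, but not with an estimated correlation (adjusted p = 0.55 for each), and no member passed by edgeR over all genes tested. The natriuretic peptide gene NPPA and the glucocorticoid-responsive gene FKBP5 had higher levels in NICM. NR4A1, an immediate early nuclear receptor, was at 138.5 ± 172 in donors and 6.18 ± 5.19 in NICM (CPM, TMM-scaled reads per 1000000, mean ± SD, n = 3 each, log2 fold -4.49 ± 0.90 with its standard error). DNAJA4, a heat shock co-chaperone, was at 508.5 ± 732 in donors and 16.7 ± 6.41 in NICM (log2 fold -4.93 ± 0.95). NRAP, a protein of myofibril assembly, was at 3400 ± 4346 in donors and 200.2 ± 34.8 in NICM (log2 fold -4.09 ± 0.81). FKBP5 was at 223 ± 205 in donors and 1002 ± 593 in NICM (log2 fold 2.17 ± 0.70), and NPPA at 26.2 ± 21.2 in donors and 124.5 ± 50.6 in NICM (log2 fold 2.25 ± 0.78). Each of these 5 genes had all samples of a group above all samples of the other (separated groups). The naming rule required this of NR4A1, DNAJA4 and NRAP. None of the 5 passed the test: the smallest adjusted p by edgeR's quasi-likelihood test was 0.225.

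The 5 genes of smallest p among those with separated groups and 16 CPM or more, all lower in NICM, were DNAJA4 (ENSG00000140403, chromosome 15, 78264086 to 78282196, on GRCh38), NRAP (ENSG00000197893, chromosome 10, 113588716 to 113664127), NR4A1, RRAD and THBS1. RRAD, a small GTPase that regulates calcium channels, had a log2 fold of -4.51 ± 0.91, and THBS1, a matrix glycoprotein, -4.91 ± 1.00. Donor replicate 1 held 8416 CPM of NRAP and 1352 of DNAJA4, against 771 and 119 in donor replicate 2, and 1014 and 53.5 in donor replicate 3. Log2 folds moved from -4.93 to -2.37 for DNAJA4, from -4.09 to -2.15 for NRAP and from -4.49 to -2.67 for NR4A1 without donor replicate 1, from -4.51 to -2.56 for RRAD and from -4.91 to -1.84 for THBS1 without donor replicate 2, and from 2.17 to 1.55 for FKBP5 without NICM replicate 2. Among the genes fixed in advance, ANKRD1 was at 2353 ± 771 in donors and 1190 ± 405 in NICM, and CORIN, the protease that activates natriuretic peptides, at 239 ± 41.6 in donors and 106 ± 18.7 in NICM, both with all NICM samples below all donors. NPPB had a log2 fold of 2.08 ± 0.79 and XIRP2, an actin-binding protein of the intercalated disc, -2.36 ± 0.78, each with overlapping groups. Log2 folds of the contractile genes MYH6 (0.34 ± 0.64), MYH7 (-0.02 ± 0.71), ACTA1 (-0.00 ± 0.73) and TTN (-0.51 ± 0.62) lay within their standard errors of 0. RYR2 (-0.45 ± 0.59), ATP2A2 (-0.58 ± 0.58), PLN (-1.16 ± 0.65), PDK4 (-0.45 ± 0.65) and ZBTB16 (0.74 ± 0.60) also had overlapping groups.

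Immediate early and heat shock genes, which respond within minutes to hours to stress, were the called lists with the lowest medians (adjusted p = 0.55 for each with an estimated correlation). All 23 measured immediate early genes were lower in NICM by their fitted fold, with a median log2 fold of -2.90, and 13 passed 0.05 adjusted over the list alone. All 16 heat shock genes were lower, with a median of -2.55, and 12 passed adjusted over the list alone. By edgeR no member of either passed when adjusted over all genes tested, whereas NR4A1 passed by DESeq2. HSPA1A averaged 66.2 CPM in donors and 8.25 in NICM, and BAG3 232 and 11.6. Without donor replicate 1 the medians were -1.21 and -1.15. Of 23 lists camera called 15, all lower in NICM, with medians of -2.90 for immediate early genes, -2.55 for heat shock genes, -0.93 for hypoxia genes, -0.86 for resident macrophage genes, -0.69 for monocyte-derived cell genes, -0.66 for mitochondrially encoded genes, -0.57 for NF-kB inflammatory genes and -0.55 for glycolysis. The other called lists had medians of -0.54 for quiescent fibroblast genes, -0.53 for cardiac stress genes, -0.42 for ribosomal proteins, -0.39 for calcium handling genes, -0.37 for sarcomere genes, -0.33 for pericyte and contractile genes and -0.11 for collagens and matrix. Over these lists the adjusted p of camera was 9.17e-29 to 0.0329 with the preset correlation, and adjusted p = 0.55 to 0.841 with an estimated correlation. The 8 lists not called had medians of -0.29 for capillary endothelial genes, -0.29 for fatty acid oxidation, -0.23 for nuclear oxidative phosphorylation genes and -0.23 for interferon response genes. They also had medians of -0.11 for endothelial activation genes, 0.04 for fibroblast activation, 0.05 for glucocorticoid response genes and 0.09 for ion channels. Median, mean and test differed in sign for ion channels and nuclear oxidative phosphorylation genes. Of the 15 calls, 10 lost the call or turned without donor replicate 3, 9 without NICM replicate 3, 5 without donor replicate 2 and 1 without NICM replicate 1. With the background subtracted 6 of the 15 kept the call and no other list was called.

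**Figure D3:**
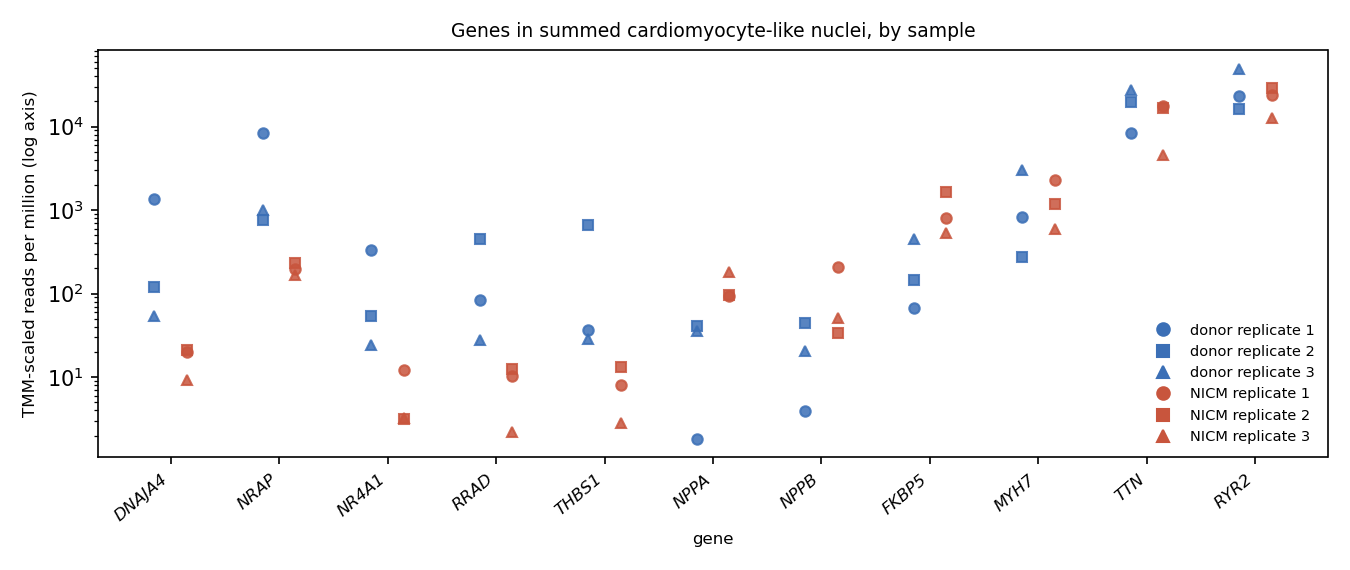
Points give TMM-scaled CPM, on a log axis, of 11 genes in the summed cardiomyocyte-like nuclei of each sample, donors in blue and NICM in red. The 5 genes on the left lie lower in all NICM samples, NPPA and FKBP5 lie higher, and MYH7, TTN and RYR2 overlap.

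By edgeR, 0 of 47782 genes passed an adjusted p of 0.05 in cardiomyocyte-like nuclei, with 1302 at an unadjusted p under 0.05. DESeq2 called 55, edgeR on library size alone 100, and limma on mean log values 0. DESeq2's adjusted p was 0.00627 for DNAJA4, 0.0112 for NRAP, 0.0145 for NR4A1 and 0.0172 for RRAD. Groups were separated in 1713 genes (3.58%, where chance gives 10%). Nuclei of this class fell in clusters by sample: each donor had a main cluster of its own and the 3 NICM samples shared 1, with 87% to 96.5% of a sample's nuclei in it. EdgeR called 28 genes without donor replicate 2, 22 without NICM replicate 2, 6 without NICM replicate 1, and 1 with donor replicate 1 and NICM replicate 3 both left out.

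Fibroblast-like nuclei had more reads of the matricellular gene CCN2 (CTGF in the files) in NICM, and fewer of KLF10, a transcription factor induced by TGF-beta. CTGF was at 39.4 ± 20.7 in donors and 327 ± 181 in NICM (log2 fold 3.05 ± 0.69), and KLF10 at 67.8 ± 17.0 in donors and 8.08 ± 1.52 in NICM (log2 fold -3.07 ± 0.49), both with separated groups. The naming rule required the separation of KLF10. GPRC5A, a membrane receptor, was at 65.9 ± 14.5 in donors and 9.42 ± 5.00 in NICM, TMEM176B at 79.8 ± 39.7 in donors and 11.6 ± 4.41 in NICM and ZNF331, a zinc finger gene, at 245 ± 120.4 in donors and 45.9 ± 14.1 in NICM. The collagen genes COL1A1 (-0.28 ± 0.77), COL1A2 (-0.03 ± 0.68) and COL3A1 (-0.25 ± 0.70) had log2 folds within their standard errors of 0.

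POSTN, a matrix protein of activated fibroblasts, was at 87.4 ± 107 in donors and 287 ± 343 in NICM (log2 fold 1.72 ± 1.04), a fold that turned in sign in another setting. FAP, a surface protease of the same state, had a log2 fold of 1.00 ± 0.50. Groups overlapped for POSTN and FAP. FKBP5 (1.80 ± 0.90), THBS4 (1.25 ± 0.85), SCN7A (0.92 ± 0.66), PCOLCE2 (0.56 ± 0.66), FN1 (0.16 ± 0.66), ELN (-0.62 ± 0.85) and MEOX1 (-0.50 ± 0.80) overlapped too. NPPA reads, at 15.4 ± 10.6 in donors and 173.5 ± 107.5 in NICM, were among the 5 of smallest p. In NICM samples their share of reads was at or above that in cardiomyocyte-like nuclei of the same sample, which held more reads each. Without NICM replicate 3 the log2 fold was 2.82. With all samples and no background subtracted, fibroblast activation genes were the only list called higher, in 17 of 27 members, with a median of 0.40 (camera adjusted p = 0.0193, and adjusted p = 0.841 with an estimated correlation). Adjusted over the list alone, 1 member passed. Among quiescent fibroblast genes, FGF7 averaged 213 CPM in donors and 14.8 in NICM, and CD248 36.5 and 6.36, both chosen after their values were seen. SCN7A (0.92 ± 0.66) and PCOLCE2 (0.56 ± 0.66), the members of that list fixed by name, had folds the other way, with overlapping groups. Camera called 10 lists here, with medians of -1.29 for immediate early genes, -1.07 for NF-kB inflammatory genes, -0.80 for hypoxia genes, -0.68 for quiescent fibroblast genes and -0.56 for resident macrophage genes. It also called lists with medians of -0.54 for glycolysis, -0.53 for heat shock genes, -0.51 for ribosomal proteins, -0.33 for endothelial activation genes and 0.40 for fibroblast activation. Adjusted p was 5.14e-12 to 0.0193 for them with the preset correlation, and adjusted p = 0.646 to 0.841 with an estimated correlation. Lists that missed the threshold, 13 in number, had medians of -0.36 for mitochondrially encoded genes, -0.24 for nuclear oxidative phosphorylation genes, -0.16 for pericyte and contractile genes, -0.15 for cardiac stress genes, -0.14 for calcium handling genes, -0.13 for monocyte-derived cell genes and -0.13 for interferon response genes. Their other medians were -0.09 for collagens and matrix, -0.08 for fatty acid oxidation, -0.04 for ion channels, -0.01 for capillary endothelial genes, 0.02 for sarcomere genes and 0.16 for glucocorticoid response genes. The signs of median, mean and test differed for cardiac stress genes and glucocorticoid response genes. The call of fibroblast activation was lost without donor replicate 1 (median 0.12), NICM replicate 1 (-0.11) or NICM replicate 2 (0.04). Of the 10 called lists, 7 lost the call or turned without NICM replicate 3, 7 without donor replicate 3, 2 without NICM replicate 1, 1 without NICM replicate 2, 1 without donor replicate 1 and 1 without donor replicate 2. Subtracting the background kept 5 of the 10 calls, and cardiac stress genes (median 0.16) and sarcomere genes (median 0.34) were newly called, higher in NICM.

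Of 48541 genes tested in fibroblast-like nuclei, edgeR called 0 (smallest adjusted p 1.00), with 1522 at an unadjusted p under 0.05. DESeq2 called 118, edgeR on library size alone 43 and limma 0. DESeq2's adjusted p was 1.09e-12 for KLF10, 0.00231 for GPRC5A and 0.049 for CTGF. Groups were separated in 2294 genes (4.73%, where chance gives 10%), and each donor and NICM replicate 1 had a main cluster of its own.

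Endothelial-like nuclei had lower levels of SELE, PLA2G2A and ADAMTS4 in NICM, although no gene passed by edgeR (smallest adjusted p 0.487). Among genes at a mean of 16 CPM or more, as these 3 are, edgeR's smallest adjusted p was 0.979. SELE, the endothelial adhesion molecule E-selectin, was at 77.0 ± 54.8 in donors and 3.72 ± 2.02 in NICM (log2 fold -4.37 ± 0.82), and ICAM1, a ligand for leukocyte integrins chosen after its values were seen, averaged 44.4 and 7.10. PLA2G2A, a secreted phospholipase, was at 76.3 ± 59.2 in donors and 3.73 ± 1.54 in NICM (log2 fold -4.35 ± 0.81), and ADAMTS4, a matrix protease, at 37.4 ± 32.6 in donors and 2.69 ± 1.55 in NICM. All 4 had every NICM sample below every donor. The naming rule required this separation of SELE, PLA2G2A and ADAMTS4, and of RGS16 and FNIP1. With 1 sample left out, log2 folds moved from -4.35 to -3.63 for PLA2G2A without donor replicate 3, from -3.80 to -2.91 for ADAMTS4 without donor replicate 2, and from -3.76 to -2.97 for RGS16 without donor replicate 1. PLA2G2A was more abundant in fibroblast-like nuclei, where it averaged 1041 in donors and 64.8 in NICM (chosen after its values were seen, groups overlapping) and was among the leading genes of clusters mostly of donor replicate 2 or 3, so its reads in endothelial-like nuclei are not shown to be of endothelial origin. Endothelial identity genes overlapped between the groups, with log2 folds of -0.49 ± 0.74 for VWF, -0.39 ± 0.97 for PECAM1 and 0.03 ± 0.96 for KDR.

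RGS16, a regulator of G protein signalling, was at 35.2 ± 28.0 in donors and 2.59 ± 1.87 in NICM, and FNIP1 (ENSG00000217128, chromosome 5, 131641714 to 131797063), a binding partner of folliculin, at 39.4 ± 2.12 in donors and 15.8 ± 1.55 in NICM (log2 fold -1.31 ± 0.33), both lower in all NICM samples. FKBP5 had a log2 fold of 1.99 ± 0.76, FLT1 -1.20 ± 0.88 and COL15A1 -1.09 ± 0.52, with overlapping groups. So had CA4 (-0.45 ± 1.06), PLVAP (-0.30 ± 0.67), ACKR1 (0.03 ± 0.79), NRG1 (0.17 ± 0.40) and IL1R1 (-0.20 ± 0.37). NF-kB inflammatory genes were lower in 21 of 26 members, and 4 passed adjusted over the list alone (adjusted p = 0.627 by camera with an estimated correlation). The 12 lists called by camera were all lower in NICM, at medians of -1.08 for immediate early genes, -1.03 for heat shock genes, -0.95 for NF-kB inflammatory genes, -0.71 for ribosomal proteins, -0.62 for glycolysis and -0.58 for quiescent fibroblast genes. Further called lists stood at -0.50 for hypoxia genes, -0.50 for nuclear oxidative phosphorylation genes, -0.42 for fatty acid oxidation, -0.39 for endothelial activation genes, -0.36 for resident macrophage genes and -0.18 for monocyte-derived cell genes. Adjusted p was 6.33e-11 to 0.0452 for them with the preset correlation, and adjusted p = 0.55 to 0.841 with an estimated correlation. Medians of the 11 lists not called were -0.52 for mitochondrially encoded genes, -0.44 for pericyte and contractile genes, -0.40 for capillary endothelial genes, -0.29 for sarcomere genes, -0.28 for calcium handling genes and -0.27 for cardiac stress genes. For the rest they were -0.08 for collagens and matrix, 0.01 for ion channels, 0.02 for interferon response genes, 0.17 for fibroblast activation and 0.36 for glucocorticoid response genes. Sign differed between median, mean and test for interferon response genes and ion channels. Among the 12 called, 10 lost the call or turned without donor replicate 3, 6 without NICM replicate 3, 3 without NICM replicate 2, 3 without donor replicate 2, 2 without NICM replicate 1 and 1 without donor replicate 1. The call was kept in 7 of the 12 with the background subtracted, and glucocorticoid response genes (median 1.06) were newly called, higher in NICM. EdgeR called 0 of 49586 genes (smallest adjusted p 0.487), with 1777 at an unadjusted p under 0.05, DESeq2 118, edgeR on library size alone 34 and limma 0. DESeq2's adjusted p was 6.35e-06 for FNIP1 and 5.00e-05 for SELE. Separated groups were seen in 2936 genes (5.92%, where chance gives 10%), and each donor had a different main cluster.

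Mural-like nuclei, all of them pericyte-like since no cluster took the smooth muscle name, had fewer NARF and CRHR2 reads in NICM. NARF (ENSG00000141562, chromosome 17, 82458180 to 82490537) was at 44.8 ± 9.32 in donors and 7.96 ± 2.85 in NICM (log2 fold -2.49 ± 0.46), KANK3 at 57.6 ± 31.4 in donors and 8.30 ± 3.49 in NICM, and CRHR2, a receptor for urocortins, at 65.6 ± 50.8 in donors and 6.62 ± 1.78 in NICM. DMAC2, an assembly factor of respiratory complex I, was at 30.9 ± 25.0 in donors and 1.63 ± 0.469 in NICM (log2 fold -4.24 ± 0.72). NPPA reads were at 26.1 ± 18.2 in donors and 243 ± 112 in NICM. These 5 genes had the smallest p among genes with separated groups and 16 CPM or more, so their separation follows from the rule. Single samples moved the log2 fold from -4.24 to -3.38 for DMAC2 and from -3.31 to -2.57 for CRHR2 without donor replicate 3. ABCC9, a subunit of ATP-sensitive potassium channels, was at 1211 ± 799 in donors and 376 ± 103 in NICM (log2 fold -1.69 ± 0.64), with overlapping groups.

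Pericyte genes fixed in advance had log2 folds of -0.58 ± 0.87 for RGS5, -1.43 ± 0.95 for PDGFRB, -0.88 ± 0.93 for NOTCH3, 0.22 ± 0.86 for ACTA2, 0.53 ± 0.80 for MYH11 and -0.01 ± 0.80 for COL4A1, all with overlapping groups. FKBP5 was at 127 ± 82.3 in donors and 399.8 ± 189.9 in NICM (log2 fold 1.65 ± 0.64). TNC, a matrix protein, averaged 7.62 CPM in donors and 47.1 in NICM. Camera called 9 lists lower in mural-like nuclei, at medians of -0.77 for hypoxia genes, -0.71 for heat shock genes, -0.70 for ribosomal proteins, -0.61 for resident macrophage genes and -0.58 for NF-kB inflammatory genes. The remaining calls had medians of -0.55 for nuclear oxidative phosphorylation genes, -0.51 for immediate early genes, -0.46 for glycolysis and -0.41 for sarcomere genes. Adjusted p was 2.90e-05 to 0.0304 for them with the preset correlation, and adjusted p = 0.838 to 0.841 with an estimated correlation. Uncalled lists, 14 of them, had medians of -0.72 for mitochondrially encoded genes, -0.54 for capillary endothelial genes, -0.40 for calcium handling genes, -0.27 for pericyte and contractile genes, -0.26 for monocyte-derived cell genes, -0.25 for fatty acid oxidation and -0.23 for endothelial activation genes. The upper part of them had medians of -0.18 for interferon response genes, -0.11 for quiescent fibroblast genes, -0.06 for cardiac stress genes, 0.05 for collagens and matrix, 0.17 for fibroblast activation, 0.22 for ion channels and 0.28 for glucocorticoid response genes. Median, mean and test disagreed in sign for cardiac stress genes and ion channels. Among the 9 called, 7 lost the call or turned without NICM replicate 3, 7 without donor replicate 3, 4 without NICM replicate 2, 3 without donor replicate 2 and 1 without NICM replicate 1. After subtraction of the background 2 of the 9 kept the call, and collagens and matrix (median 0.37) were newly called, higher in NICM. Among 39752 genes, edgeR called 0 (smallest adjusted p 0.710), with 1790 at an unadjusted p under 0.05, DESeq2 276, edgeR on library size alone 2 and limma 0. DESeq2's adjusted p was 2.51e-06 for NARF and 3.12e-06 for DMAC2. The groups were separated in 2740 genes (6.89%, where chance gives 10%), and each donor had a different main cluster.

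Myeloid-like nuclei had fewer reads of the monocyte chemoattractant CCL2 in NICM, and a median log2 fold of -1.40 over genes of monocyte-derived cells. Camera called that list with a preset correlation, but adjusted p = 0.673 with an estimated correlation and 0.948 by fry, and none of its members passed by edgeR. A cluster of 84 nuclei with myeloid as its best class stayed unnamed and is not in these sums. FCN1, a member of that list, was among its leading genes. CCL2 was at 191 ± 127 in donors and 3.42 ± 4.16 in NICM (log2 fold -5.79 ± 1.10). It was lower in other classes too, at means of 368 in donors and 45.6 in NICM in fibroblast-like nuclei, where it was a leading gene of a cluster mostly of donor replicate 1, and of 99.6 in donors and 9.16 in NICM in endothelial-like nuclei (chosen after the values were seen, groups overlapping in both), so the change is not shown to be one of myeloid nuclei alone. VCAN, abundant in monocytes, averaged 706 CPM in donors and 64.8 in NICM, and the lysozyme gene LYZ 212 and 13.4, the groups overlapping in VCAN and separated in LYZ. HIF1A, the oxygen-regulated transcription factor, averaged 365 and 52.1. The scavenger receptors CD163 (log2 fold 0.17 ± 0.80) and MRC1 (0.51 ± 0.70), carried by tissue macrophages, overlapped between the groups.

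RFX2 (ENSG00000087903, chromosome 19, 5993164 to 6199572), a transcription factor, was at 127 ± 11.2 in donors and 24.9 ± 0.935 in NICM (log2 fold -2.35 ± 0.42). BCL3, a regulator of NF-kB, was at 32.8 ± 12.4 in donors and 3.58 ± 2.11 in NICM, ADAMTS1 at 33.4 ± 17.3 in donors and 4.35 ± 1.33 in NICM and RHBDD3 at 32.3 ± 14.5 in donors and 4.43 ± 0.966 in NICM. These 4 genes and CCL2 had every NICM sample below every donor, since the naming rule required separated groups. LYVE1, of resident macrophages, had a log2 fold of -2.01 ± 0.82, F13A1 -1.19 ± 0.67, IL1B -2.26 ± 0.95 and CCR2 -1.25 ± 0.82, with overlapping groups. FKBP5 was at 779 ± 953.5 in donors and 2197 ± 1257 in NICM. SPP1 (-2.92 ± 1.62), TREM2 (-0.48 ± 1.47) and FOLR2 (-0.38 ± 1.03) overlapped as well, and SPP1 turned in sign without donor replicate 3 (log2 fold 1.19). Lower in NICM by camera were 10 lists, with medians of -1.40 for monocyte-derived cell genes, -1.11 for NF-kB inflammatory genes, -1.06 for immediate early genes, -0.97 for hypoxia genes and -0.86 for resident macrophage genes. Others called had medians of -0.86 for heat shock genes, -0.84 for capillary endothelial genes, -0.71 for glycolysis, -0.57 for ribosomal proteins and -0.28 for pericyte and contractile genes. Adjusted p was 1.37e-06 to 0.0433 for them with the preset correlation, and adjusted p = 0.673 to 0.841 with an estimated correlation. The 13 remaining lists had medians of -0.45 for interferon response genes, -0.39 for calcium handling genes, -0.23 for fatty acid oxidation, -0.21 for nuclear oxidative phosphorylation genes, -0.20 for quiescent fibroblast genes, -0.13 for mitochondrially encoded genes and -0.01 for collagens and matrix. The higher ones had medians of 0.02 for sarcomere genes, 0.02 for endothelial activation genes, 0.04 for fibroblast activation, 0.11 for ion channels, 0.23 for cardiac stress genes and 0.35 for glucocorticoid response genes. For collagens and matrix, endothelial activation genes, ion channels and sarcomere genes, median, mean and test differed in sign. From these 10 calls, 6 lost the call or turned without donor replicate 3, 4 without NICM replicate 3, 4 without donor replicate 2 and 1 without NICM replicate 2. Of the 10, 3 kept the call with the background subtracted, and nuclear oxidative phosphorylation genes (median 0.37), cardiac stress genes (median 0.72) and glucocorticoid response genes (median 0.72) were newly called, higher in NICM. No gene of 42757 passed by edgeR (smallest adjusted p 0.915), a count of 0, with 2125 at an unadjusted p under 0.05. DESeq2 called 358, edgeR on library size alone 57, edgeR on nuclei thinned to 5000 reads 1, and limma 0. DESeq2's adjusted p was 1.13e-10 for RFX2 and 8.14e-06 for CCL2. Separated groups occurred in 3251 genes (7.6%, where chance gives 10%). Donor replicate 1 and NICM replicate 3 shared a main cluster, as did donor replicates 2 and 3, and NICM replicates 1 and 2.

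Summed over all nuclei, NPPA and CTGF were higher in NICM, and CCL2, NR4A3, NRAP and RRAD lower, with separated groups. The naming rule required the separation of all of these but NPPA. NPPA was at 22.3 ± 16 in donors and 173 ± 95.3 in NICM (log2 fold 2.96 ± 0.72), and NPPB, the gene of the second natriuretic peptide of the ventricle, at 10.3 ± 7.67 in donors and 58.4 ± 64.0 in NICM, also separated. CTGF was at 16.2 ± 4.34 in donors and 106 ± 66.4 in NICM (log2 fold 2.71 ± 0.63), CCL2 at 148 ± 97.4 in donors and 15.1 ± 13.8 in NICM (log2 fold -3.30 ± 0.75) and NR4A3 at 292.5 ± 433.5 in donors and 12.9 ± 1.06 in NICM. NRAP was at 1123 ± 1416 in donors and 88.1 ± 35.4 in NICM and RRAD at 65.1 ± 77.3 in donors and 4.58 ± 3.38 in NICM. A single sample decided much of some of these values, with log2 folds that moved from -3.30 to -2.71 for CCL2 and from -3.83 to -2.18 for RRAD without donor replicate 2, from -4.51 to -1.63 for NR4A3 and from -3.67 to -1.81 for NRAP without donor replicate 1, and from 2.50 to 1.06 for NPPB without NICM replicate 1. FKBP5 had a log2 fold of 1.90 ± 0.75, ANKRD1 -0.89 ± 0.59, POSTN -0.13 ± 0.76, COL1A1 -0.05 ± 0.65, MYH6 0.09 ± 0.67 and MYH7 -0.06 ± 0.75, with overlapping groups.

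NPPA reads were not confined to cardiomyocyte-like nuclei. In NICM samples the NPPA level in fibroblast-, endothelial-, mural- and myeloid-like nuclei was 1.06 to 2.02 times that in cardiomyocyte-like nuclei of the same sample. MYL2, a sarcomere transcript, stood at 1.26 to 2.09 times its cardiomyocyte level there, and MYH7 at 0.16 to 0.317 times. TTN and RYR2 reached at most 0.0676 and 0.0265 times theirs in NICM samples, and 0.0853 and 0.0305 times in donors. The spread was wider in donors, at 0.52 to 4.78 times for NPPA. It was 0.67 to 3.46 times for MYL2 and 0.161 to 1.06 times for MYH7. All these levels are shares of the reads of a class. Clusters of cardiomyocyte-like nuclei had 2.20 to 2.70 times the depth of their samples. A higher share in another class therefore does not mean more reads of the transcript per nucleus.

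**Figure D4:**
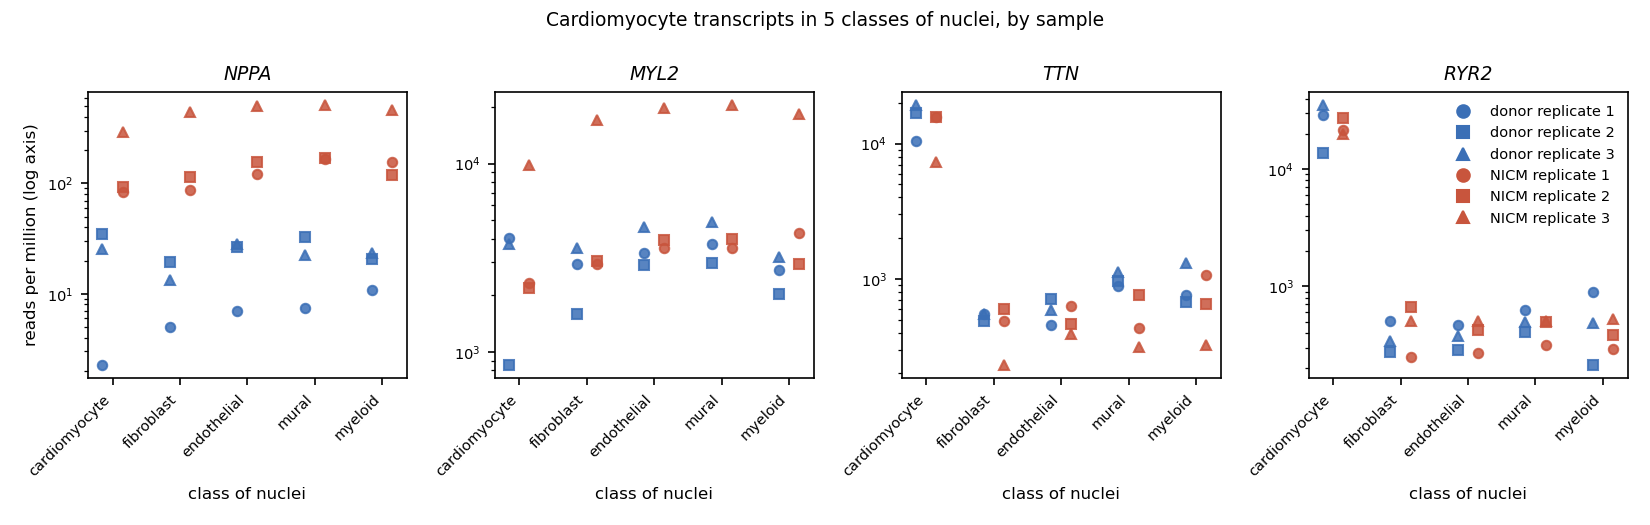
Points give CPM, on a log axis, of 4 cardiomyocyte transcripts in 5 classes of nuclei of each sample, donors in blue and NICM in red. NPPA lies in the other 4 classes at 1.06 to 2.02 times its level in cardiomyocyte-like nuclei of the same NICM sample and at 0.52 to 4.78 times in donors, while TTN and RYR2 are highest in cardiomyocyte-like nuclei of every sample.

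Over all nuclei, camera called 16 lists, all lower in NICM, with medians of -1.11 for heat shock genes, -1.09 for NF-kB inflammatory genes, -1.05 for immediate early genes, -0.71 for pericyte and contractile genes, -0.60 for resident macrophage genes, -0.59 for monocyte-derived cell genes, -0.52 for hypoxia genes and -0.52 for glycolysis. Its other calls had medians of -0.45 for mitochondrially encoded genes, -0.45 for ribosomal proteins, -0.43 for quiescent fibroblast genes, -0.42 for endothelial activation genes, -0.39 for calcium handling genes, -0.33 for sarcomere genes, -0.31 for capillary endothelial genes and -0.27 for fatty acid oxidation. Adjusted p was 2.21e-19 to 0.0467 for them with the preset correlation, and adjusted p = 0.55 to 0.841 with an estimated correlation. Not called were 7 lists, with medians of -0.48 for cardiac stress genes, -0.29 for nuclear oxidative phosphorylation genes, -0.05 for collagens and matrix and -0.02 for ion channels. Also not called were lists with medians of -0.02 for interferon response genes, 0.21 for fibroblast activation and 0.32 for glucocorticoid response genes. Over these 16 calls, 11 lost the call or turned without NICM replicate 3, 10 without donor replicate 3, 4 without donor replicate 2 and 1 without NICM replicate 2. Among the 16, 7 kept the call with the background subtracted, and glucocorticoid response genes (median 0.57) were newly called, higher in NICM. For single genes, edgeR called 0 of 54955 (smallest adjusted p 1.00), with 1092 at an unadjusted p under 0.05, DESeq2 17, edgeR on library size alone 0 and limma 0. The groups were separated in 1821 genes (3.31%, where chance gives 10%). With donor replicate 1 and NICM replicate 3 left out together, edgeR called 19 genes, 50 without NICM replicate 3, 11 without donor replicate 1, 5 without NICM replicate 2 and 4 without NICM replicate 1.

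**Figure D5:**
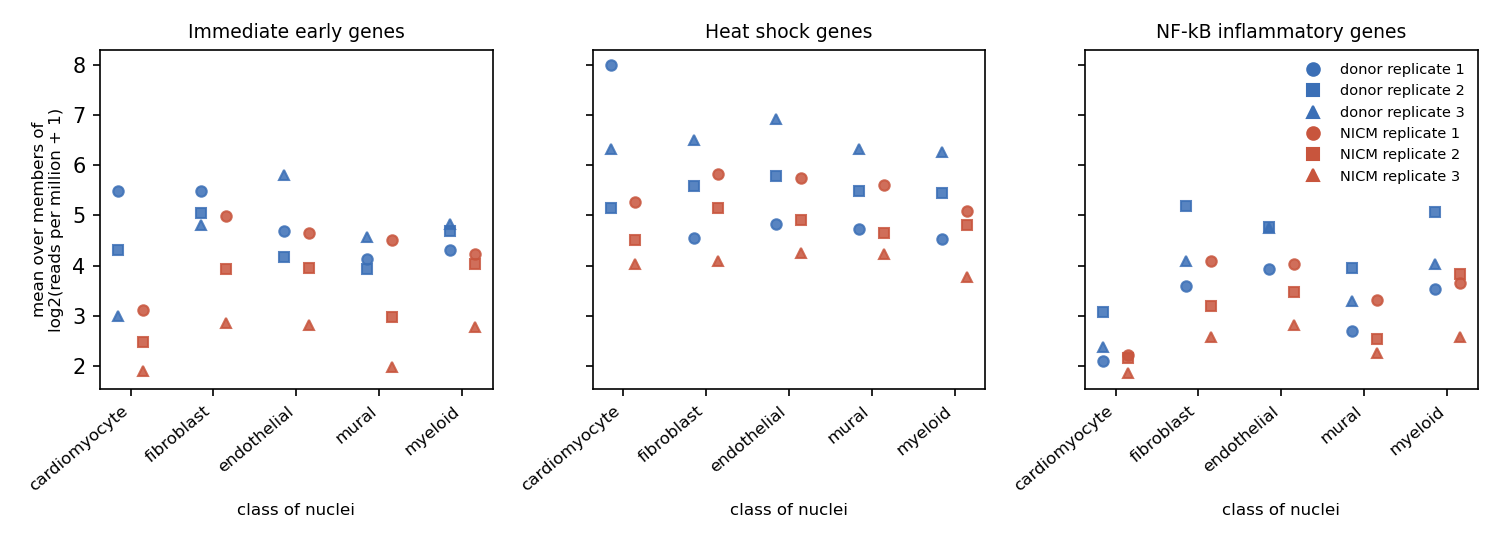
Points give the mean over the members of a list of log2(TMM-scaled CPM + 1) in 5 classes of nuclei of each sample, donors in blue and NICM in red, for immediate early, heat shock and NF-kB inflammatory genes. The highest heat shock value is that of donor replicate 1 in cardiomyocyte-like nuclei, and NICM replicate 3, the sample with the highest background percent, is lowest in each class and list.

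The difference between cardiomyocyte-like and fibroblast-like nuclei in their response was tested with both sums of each sample kept together. EdgeR called 0 of 52045 genes, with 1962 at an unadjusted p under 0.05, and DESeq2 called 162. A response of DNAJA4 or KLF10 that differs between these classes is therefore not shown by edgeR. With each sample left out in turn edgeR's count was 0.

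Limits of precision bear on all 6 comparisons. In counts simulated at the spread of these samples, genes changed by a fold of 2 were recovered in 0% and those changed by a fold of 4 in 0% to 7%, so a real change of either size would mostly be missed. Of 138 camera calls possible, 72 were made with the preset correlation and 0 with an estimated correlation or by fry, and 15 were made in each of the 6 fits that leave out 1 sample. With the background subtracted 30 of the 72 kept the call and 8 others were newly called, all higher in NICM, so that 9 of 38 calls were higher. Called in each fit that leaves out 1 sample were immediate early genes in all classes except mural, NF-kB inflammatory genes in fibroblast-like and endothelial-like nuclei, and heat shock genes in cardiomyocyte-like nuclei. Over all nuclei they were immediate early, heat shock, NF-kB inflammatory and monocyte-derived cell genes. Monocyte-derived cell genes were also called in each fit of cardiomyocyte-like and myeloid-like nuclei, resident macrophage genes of cardiomyocyte-like nuclei, and hypoxia genes of myeloid-like nuclei.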

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

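The tests of genomic DNA and of sequencing depth were fixed before their results were seen. Those of family genes by overlap, donor replicate 1, dilution by background reads, the barcode sets, free RNA, a second nucleus and the other splits of the samples were chosen after the result was seen.

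Barcodes over the mitochondrial limit entered no comparison. With the limit lifted, 1117 of 1385 such barcodes fell in clusters that took a name. Clustering places each barcode in some cluster and most nuclei lie in named clusters, so this count does not show that these barcodes carry the expression of those classes. The mast name took 347 of them, and in that clustering it covered 3.37% of donor and 5.72% of NICM barcodes, against 0.637% and 0.199% with the limit, while no cluster took the lymphoid or lymphatic name, so it is not read as a cell type there. Further barcodes numbered 274 in the endothelial-like, 145 in the pericyte-like, 116 in the fibroblast-like, 89 in the myeloid-like, 78 in the endocardial-like and 43 in the cardiomyocyte-like class. NICM replicate 1 held 677 of the 1385, donor replicates 2 and 3 held 371 and 320, NICM replicate 2 held 17, and donor replicate 1 and NICM replicate 3 held 0.

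Donor replicate 1, NICM replicate 2 and NICM replicate 3 had more genes per nucleus than the other 3 samples. NICM replicate 2, at 12639, stood close to donor replicate 2, at 12603.5. Depth per nucleus is argued against as the cause of more genes in the 3 samples. Their median reads were the lower ones, at 244801, 232446 and 259660. Donor replicates 2 and 3 and NICM replicate 1 had 300074, 315890 and 367450. With each nucleus thinned to 5000 reads, the lowest of the 3 medians still exceeded the highest of the others by 96.0 genes. Reads from genomic DNA, spread over genes by length, may account for it, since the median density of reads over olfactory receptor genes was 3.06 times as high in these 3 samples, that over keratin-associated protein genes 2.82 times, over beta-defensin genes 2.72 times and over taste receptor genes 2.10 times, and within each of these 3 samples the families were at most 1.85-fold apart. Pooled over all members they were up to 7.19-fold apart, past the bound of 5 written beforehand, but that bound did not allow for members under other genes: in NICM replicate 3, olfactory receptor genes over 3 kb stood at an RPKM (reads per kb, scaled to total reads) of 0.142 where fully under other genes and 0.522 where overlapping none, and pooled over the members that overlap no other gene the families were at most 1.99-fold apart. Pooled taste receptor genes missed the ratio above 2 foreseen for each family, at 1.09 over all members and 1.34 over the 7 that overlap no other gene. The read density below which 20% of protein-coding genes over 300 kb lay was 0.980 to 1.18 of the olfactory density. For protein-coding genes of up to 3 kb it was 0.190 to 0.343. A source other than DNA, such as unspliced RNA, therefore stays open, and no biological explanation was tested, since both groups hold such samples.

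In cardiomyocyte-like nuclei, immediate early and heat shock genes had medians of -2.90 and -2.55 log2 in NICM against donors. With the background subtracted the medians were -3.52 and -3.40, lower than before. This cannot decide on dilution by background reads. Short genes with few reads stood well below the olfactory density, so the subtraction can take too many reads from them. Donor replicate 1 as the only source cannot be told apart from the group: without it the difference of mean log2 levels was -1.16 for immediate early genes (-1.76 with all 6 samples), -1.73 times its standard error of 0.67, and -1.14 for heat shock genes (-1.89 with all 6), -1.77 times its standard error. This left 65.6% and 60.1% of the differences, more than donor replicate 1 alone would leave, but within 2 standard errors of 0. The barcode set cannot be told apart from the group either, since samples of different groups shared 0 barcodes and those of a group 813 to 954. The disease itself and the way the tissue was obtained, which differed with the group, stay open as untested explanations.

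NPPA reads were higher in NICM in fibroblast-like and mural-like nuclei as well as in cardiomyocyte-like nuclei. A second, cardiomyocyte, nucleus in the same well is argued against: TTN and RYR2 in other classes reached at most 0.068 of their level in cardiomyocyte-like nuclei in NICM samples and 0.0853 in donors. Free cardiomyocyte RNA in the wells may account for the reads in other classes of NICM samples. The lowest NPPA level there was 1.06 times and the highest 2.02 times that in cardiomyocyte-like nuclei of the same sample. These levels are shares of reads, and cardiomyocyte-like nuclei held more reads each. The ratios therefore do not show that other nuclei held as many NPPA reads per nucleus, which was not tested. In NICM samples MYL2 was at 1.26 to 2.09 times, while MYH7 stood at 0.160 to 0.317 times. The test covered NICM samples alone, and donors had NPPA at 0.52 to 4.78 times, with the other 4 classes of a donor up to 2.19 times apart against 1.91 in NICM, so an even spread of such RNA is not shown there. Whether such RNA adds to PLA2G2A reads of endothelial-like or CCL2 reads of myeloid-like nuclei was not tested. Whether NPPA within cardiomyocyte-like nuclei differs beyond such RNA stays open, as does the disease as the untested source of its higher level.

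The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. In cardiomyocyte-like, fibroblast-like and myeloid-like nuclei and for the effect difference, the real split gave 0 edgeR calls and the highest of the other splits 0. In endothelial-like nuclei, mural-like nuclei and all nuclei the real split gave 0 and the highest other 3061, 1166 and 2313. With a real count of 0, all 10 splits reach it by construction, so the number of splits that do decides nothing. The highest counts came from the split that set donor replicate 1, NICM replicate 2 and NICM replicate 3 apart. Those samples had more background reads and also lower median mitochondrial reads, at 0.617%, 2.05% and 0.996%. Donor replicates 2 and 3 and NICM replicate 1 stood at 4.44%, 5.75% and 5.47%. This points to a structure of the samples that follows background and mitochondrial reads alike, and the split cannot part these traits. Camera called 72 lists in the real split and 110 in that same split, the highest of the others, and 6 of the 10 splits gave 72 or more.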

How the results depend on the processing

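Chosen after the result was seen were the settings with genes at 16 CPM or more only, the background as a covariate, the background subtracted, donor replicates 2 and 3 against NICM replicates 1 and 2, and all nuclei without the clusters led by PRAME. The others were planned. No paired analysis was possible because the labels pair no donor with a NICM sample. The lowest median depth per nucleus was 232446 reads, amplified copies included, and whether depth limits the calls was examined only by thinning. The spread between 3 samples limits what can pass.

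EdgeR's 0 calls became 55, 118, 118, 276, 358 and 17 with DESeq2 in cardiomyocyte-like, fibroblast-like, endothelial-like, mural-like, myeloid-like and all nuclei, and 162 for the effect difference. With library size alone they became 100, 43, 34, 2 and 57 in the first 5 of these. Thinning gave 1 call in myeloid-like nuclei. Donor replicates 2 and 3 against NICM replicates 1 and 2 gave 1 in cardiomyocyte-like and 19 in all nuclei. With 1 sample left out, calls ran from 0 to 28 in cardiomyocyte-like and 0 to 50 in all nuclei, and were 0 in the other classes. No other setting called a gene, and the cause was not tested. Of 95 named values, 26 passed with DESeq2, 25 with library size alone, 1 with thinning and 0 with limma, 6 without NICM replicate 3, 3 without NICM replicate 2, 3 without donor replicate 2, 1 without donor replicate 1 and 1 with donor replicates 2 and 3 against NICM replicates 1 and 2.

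The group difference in share moved by at most 1 SD between samples, apart from these. With no mitochondrial limit the mast-like share was 2.36 percentage points higher in NICM, a reversal, and no cluster took the lymphatic or lymphoid name (difference 0 in each). With clusters made per sample, differences were 0.229 for adipocyte-like and -0.963 for neuronal-like nuclei, of unchanged sign. Within 1 SD, with 1 sample left out, the difference changed sign for endothelial-like (-4.22 to 3.62), neuronal-like (-0.600 to 0.131), mast-like (-0.756 to 0.00992) and unnamed nuclei (-3.27 to 12.9), and it ran from 2.10 to 9.22 for fibroblast-like, 1.43 to 5.14 for myeloid-like, -4.85 to -1.89 for endocardial-like, 0.507 to 2.07 for lymphoid-like, 0.730 to 1.62 for lymphatic-like and 0.602 to 1.49 for adipocyte-like nuclei. The sign also changed with the limit at 5% for endothelial-like, mast-like and neuronal-like nuclei, and for endothelial-like nuclei with at least 1000 genes and among named nuclei. Names within samples were less stable than the group differences, since a sample of each group lost names alike. With no mitochondrial limit, pericyte-like nuclei fell from 171 to 28 in donor replicate 1 and from 183 to 11 in NICM replicate 3. With clusters made per sample, unnamed nuclei rose from 597 to 1046 and from 652 to 1189 in these samples. The cause was not tested. The quality measures moved by less than 1 SD in all settings run, and each changed sign with some sample left out. Of 37 named values with separated groups, 17 had a fold over 1.5 times smaller with 1 sample left out.

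The 72 list calls became 38 with the background subtracted, 0 with an estimated correlation, 0 with fry, 52 with thinning and 40 to 105 with 1 sample left out, and the cause was not tested. With the background subtracted 30 of the 72 kept the call, and 9 of the 38 were higher in NICM against 1 of 72. Thinning kept 44 of the 72, with 27 lost or turned and 8 new, and 7 of its 52 were higher. Without NICM replicate 3 or donor replicate 3, 28 and 22 of the 72 kept the call, and 18 others were newly called each time, all higher. In 23 of the 72 the median changed sign in at least 1 such fit, in 18 without donor replicate 3 and 7 without NICM replicate 3, and 9 passed 0 by at least 0.1. From lowest to highest, medians of these ran from -0.70 to 0.17 for fatty acid oxidation in all nuclei, -1.04 to 0.43 for quiescent fibroblast genes in all nuclei, -1.09 to 0.55 for sarcomere genes in all nuclei, -0.88 to 0.20 for pericyte and contractile genes in cardiomyocyte-like nuclei, -0.66 to 0.61 for sarcomere genes in cardiomyocyte-like nuclei, -0.11 to 0.79 for fibroblast activation in fibroblast-like nuclei, -0.90 to 0.18 for heat shock genes in fibroblast-like nuclei, -1.58 to 0.18 for quiescent fibroblast genes in fibroblast-like nuclei and -0.76 to 0.16 for sarcomere genes in mural-like nuclei. Other lists, none of the 72, were called in the opposite direction with 1 sample left out. For collagens and matrix they ran from -0.43 to 0.29 in all nuclei, -0.54 to 0.26 in fibroblast-like nuclei and -0.63 to 0.71 in mural-like nuclei. For interferon response genes they ran from -0.66 to 0.29 in all nuclei, -0.80 to 0.43 in endothelial-like nuclei and -0.60 to 0.30 in fibroblast-like nuclei. For nuclear oxidative phosphorylation genes they ran from -0.65 to 0.30 in all nuclei, -0.59 to 0.70 in cardiomyocyte-like nuclei, -0.65 to 0.34 in fibroblast-like nuclei and -0.70 to 0.36 in myeloid-like nuclei. For capillary endothelial genes they ran from -1.32 to 0.71 in endothelial-like nuclei. For cardiac stress genes they ran from -1.06 to 0.46 in endothelial-like nuclei. For sarcomere genes they ran from -0.83 to 0.34 in endothelial-like nuclei. For glucocorticoid response genes they ran from -0.43 to 0.59 in fibroblast-like nuclei and -0.70 to 0.80 in mural-like nuclei. For mitochondrially encoded genes they ran from -0.99 to 0.40 in myeloid-like nuclei. Nuclear oxidative phosphorylation genes in myeloid-like nuclei were at 0.37 with the background subtracted. The log2 fold of POSTN, fibroblast-like nuclei, ran from -0.0376 to 3.49, and that of SPP1, myeloid-like nuclei, from -4.255 to 1.19, with 0.95 when the background was a covariate.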

Other observations

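The clusters below were singled out after their values were seen. A cluster of 84 unnamed nuclei was led by CSF3R, SLC11A1, IL1R2, FCN1 and MYO1F. CSF3R is the receptor for granulocyte colony-stimulating factor, and IL1R2 a decoy receptor for interleukin 1. Donor replicates 1 to 3 held 3, 26 and 12 of these nuclei, and NICM replicates 1 to 3 held 28, 15 and 0. Among nuclei named mast-like, TPSAB1 and TPSB2, the mast cell tryptases, led a cluster of 46 nuclei, with 0, 6 and 27 in the donors and 0, 13 and 0 in NICM.

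A pair of unnamed clusters was led by PRAME, with 136 and 105 nuclei and medians of 4022 and 1878 genes. The first held 1, 22 and 43 nuclei of donor replicates 1 to 3 and 36, 34 and 0 of NICM replicates 1 to 3, and the other 45, 0 and 0 and 0, 13 and 47. EdgeR called 0 genes in all nuclei with these clusters left out. The sources do not say whether control cells were dispensed with the tissue nuclei, and these clusters are counted among the kept, unnamed nuclei.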
